A study of Homo sapiens with 2 samples.

How the data were processed

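The series measured gene expression by RNA sequencing in 2 libraries of THP-1-derived macrophages, 1 labelled as transfected with FSTL1 and 1 labelled as negative control. Per the labels' protocols, mRNA was isolated with oligo(dT) beads and libraries were made with a SMARTer mRNA kit. The aligner, the counting program and their settings are not given in the sources used here, and neither is whether counting used strand. The submitters' processing notes name only the mouse build mm10, but the deposited table holds human Ensembl gene IDs. Of its 61806 IDs, 58254 (94.3%) are in the GENCODE human annotation used here, and 99.98% of those overlap their GRCh38 position, so coordinates are given as GRCh38 gene bodies from the deposited table.

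The deposited table gives raw counts per gene, per the file headers, with 1 column per sample, and the count totals of 16855184 and 18731007 are the depth of the 2 libraries. It also gives FPKM values made by the authors. Checked against the table, each of the 123612 FPKM values equals the count divided by the table's exonic gene size in kilobases and by the summed gene counts of the library, in the usual FPKM scaling, within 0.006. The table has no gene types, and GENCODE gene types were used where protein-coding genes are named. Without strand, reads of overlapping and antisense genes cannot be told apart, and amplified reads without molecular identifiers are not independent molecules.

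The main quantity was the log2 ratio of (FPKM + 1), library labelled FSTL1 over control, for genes with at least 1 FPKM in at least 1 library. No test between groups was possible with 1 library each, and no p-values were computed. From the counts, the ratio of CPM values (counts scaled to the library total) was given with an exact conditional (Clopper-Pearson) 95% interval, and a count of 0 was taken to allow up to 3 counts. For 40 gene lists, the median of the measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Lists with fewer than 5 measured members have summed counts only. The groups, gene lists, quantities and rule for named genes were set before the data were examined. That rule took FSTL1, CD86 and MRC1, then the 12 genes with the largest and the 12 with the smallest log2 ratio, then 4 members of each list outside the central 95% of its random lists and 3 members of the M2, M1, receptor and TGF-beta lists. Because the rule by size took only short noncoding genes, a further rule was added after the values were seen, ranking protein-coding genes by the interval bound nearest to no difference and taking 15 per direction. COL1A1, COL1A2, COL3A1, COL5A1, COL11A1, KIT, POSTN, GRPR, IGFBP3, ADAMDEC1, NME8, NPIPA7, SYT12, CLEC5A, GPR82, KRT18 and RASGEF1C are named by it. TGM2, FCER1A, CSF3R, COL4A1, COL4A2, ALDOC, STARD4, MT-ATP8, MT-ATP6, IL6, IL12B, FABP4, CAP1, PPT1 and the genes named around CAP1 were likewise chosen after their values were seen.

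The interval and list procedures were tested on simulated counts, drawn for each gene independently with Poisson error from the pooled proportions of the 2 libraries. The simulation holds no differences between cultures and no genes that vary together. It therefore checks the computation, not the error rates in the real libraries. With 200 of the 12120 genes of at least 100 reads changed 2-fold, 100% of them had intervals excluding no difference. So did 4.48% of the unchanged genes. Lists of 20 genes were drawn from the more highly expressed of 12765 genes. Of 200 unchanged lists, 5% fell outside the central 95%, and 100% of lists lowered by 0.3 were found. Smaller shifts were not simulated. Alternatives set before the data were examined were pseudocounts of 0.1 and 5, 3 scalings (TPM, median ratio and upper quartile), other FPKM minimums, folds of 1.5 and 4, counting intervals, means over members and random lists without matching. Alternatives added afterwards were protein-coding genes only, at least 100 reads, and removal of trends with GC content and gene length. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.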

Results

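Poly(A)-selected RNA was sequenced from macrophages derived from THP-1, a human monocytic leukaemia line that the phorbol ester PMA turns into adherent macrophage-like cells. The series holds 2 libraries, 1 per group. The first is labelled as transfected with FSTL1, which encodes follistatin-like 1, a secreted glycoprotein. The second is labelled as a negative control that received si-NC, a control small interfering RNA. The comparison addresses whether FSTL1 affects the polarization of these cells towards the M1 (classically activated) or M2 (alternatively activated) state. The gene counts summed to 16855184 in the library labelled FSTL1 and to 18731007 in the control library, and 26192 and 26272 of the 61806 genes had at least 1 read. With 1 library per group no difference has a replicate check, and all intervals given are exact 95% intervals that cover counting error only.

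FSTL1 was barely detected in either library and was not lower in the library labelled FSTL1. The gene (ENSG00000163430, chromosome 3, 120392293 to 120450993, minus strand, GRCh38) had 40 reads there and 27 in the control, or 0.28 and 0.17 FPKM. The ratio of CPM values was 1.65 (0.986 to 2.79), so a difference was not detectable at this depth. The labels do not say whether an siRNA against FSTL1 or an FSTL1 expression plasmid was used. Within counting error the ratio lay between 0.986 and 2.79, so neither a clear loss nor a large gain of FSTL1 RNA was seen. The count alone does not settle which of them was used. The sample titles carry the suffix M2, whereas the series description speaks of sequencing unpolarized M0 cells and names no control library. Every direction below is therefore that of the library labelled FSTL1 relative to the library labelled negative control, not of a known loss or gain of FSTL1.

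Of the 2 surface markers that the study read out by flow cytometry, CD86 was lower in the library labelled FSTL1, whereas whether MRC1 differed beyond counting error depended on the scaling. CD86, a costimulatory molecule used as an M1 marker (ENSG00000114013, chromosome 3, 122055362 to 122121139, plus strand), was 1.43-fold lower in the library labelled FSTL1 (1.30 to 1.58), with 10.96 against 15.70 FPKM and 635 against 1011 reads. MRC1, which encodes the M2 marker CD206 (ENSG00000260314, chromosome 10, 17809348 to 17911164, plus strand), was 1.44-fold higher (1.01 to 2.06), at the low level of 0.86 against 0.60 FPKM and 75 against 58 reads. The lower bound of its ratio was 0.981 on the TPM scale and 0.983 with upper quartile scaling, so the interval included no difference under both. On the scale of log2(FPKM + 1), which understates differences of low genes, the differences were -0.48 for CD86 and 0.22 for MRC1.

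**Figure D1:**
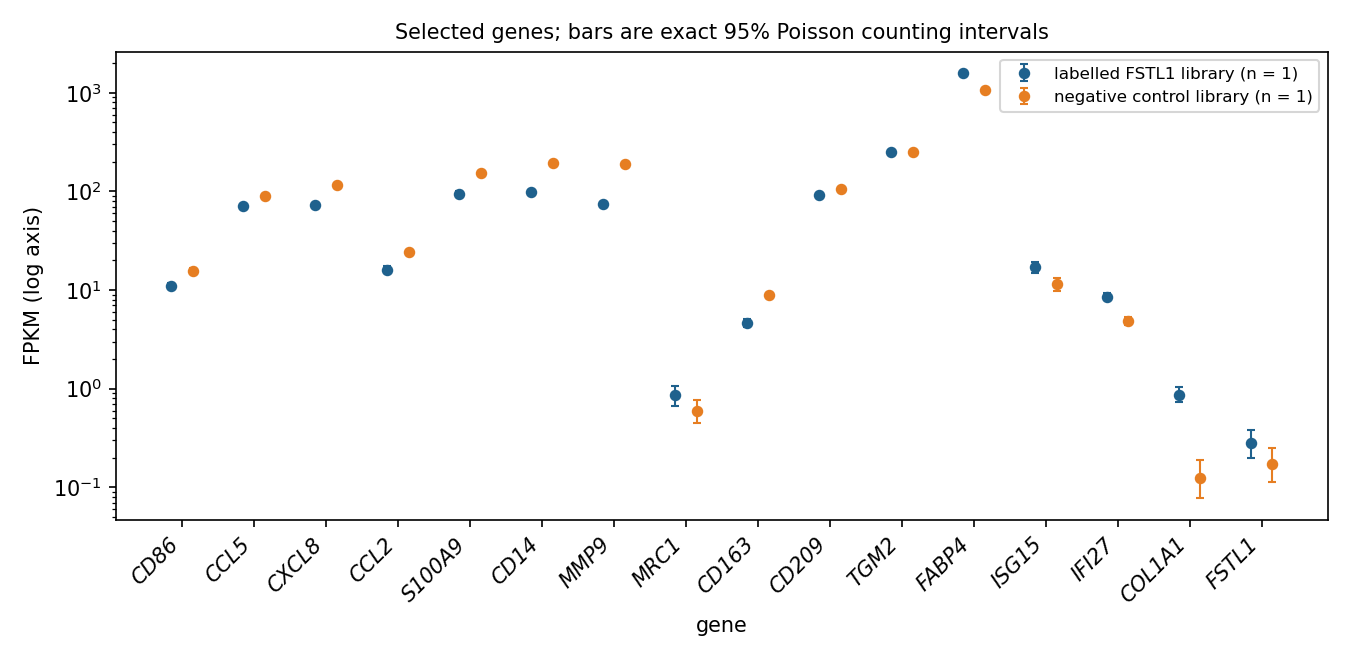
FPKM (log axis) of 16 selected genes in the library labelled FSTL1 (blue) and the negative control library (orange), 1 library each, with exact 95% Poisson counting intervals as bars. MMP9 lay at 74.85 against 190.17 FPKM and CD86 at 10.96 against 15.70 FPKM, while FSTL1 stayed at 0.28 and 0.17 FPKM with overlapping intervals.

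Most protein-coding genes differed little. MMP9, a gelatinase secreted by activated macrophages (ENSG00000100985, chromosome 20, 46008908 to 46016561, plus strand), was 2.54-fold lower (2.44 to 2.65), with 2947 against 8321 reads. MMP8, the neutrophil collagenase, was 3.24-fold lower (2.36 to 4.53). IGFBP3, a binding protein of insulin-like growth factors, was 2.49-fold lower (2.05 to 3.03), and the macrophage protease gene ADAMDEC1 was 2.07-fold lower (1.88 to 2.29). Ranked by the interval bound nearest to no difference, the lower genes also held SYT12 with 0 against 13 reads, CLEC5A with 4 against 34, GPR82 with 28 against 119, KRT18 with 2 against 22 and RASGEF1C with 8 against 44. The higher genes of that ranking were all below 1 FPKM. Besides COL1A1, COL1A2 and COL3A1, given with the matrix genes, they held COL5A1 with 18 against 0 reads and KIT with 15 against 0. COL11A1 had 26 against 3, POSTN 49 against 9 and GRPR 10 against 0. IGFBP3, ADAMDEC1 and the genes of this ranking were chosen after their values were seen. Reads of CLEC5A, GPR82 and KRT18 may belong to overlapping genes on the opposite strand, and so may those of GRPR.

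Of 12968 genes with at least 1 FPKM in at least 1 library, 146 were at least 2-fold higher and 127 at least 2-fold lower on the log2(FPKM + 1) scale. Noncoding genes made up 146 and 119 of these, and the median gene had an exonic length of 107 and 102 bases and 3 and 4 reads over both libraries. The 12 highest and the 12 lowest were U6 and U7 small nuclear RNA copies, Y RNAs, microRNAs, small nucleolar RNAs and a ribosomal pseudogene, 59 to 146 bases long and with 3 to 13 reads each over both libraries, and are not described singly. Restricted to protein-coding genes, 0 were at least 2-fold higher and 5 at least 2-fold lower, which were MMP9, MMP8, ADAMDEC1, NME8 and NPIPA7, a member of a family of near-identical copies. From the counts, 10948 protein-coding genes had at least 100 reads over both libraries, and the central 95% of their log2 CPM ratios ran from -0.41 to 0.49. Of these genes, 10 were at least 2-fold higher and 13 at least 2-fold lower, and the counting interval excluded no difference for 1648 higher and 1890 lower genes, 32.3% of them. That share compares these 2 libraries and not the conditions, since differences between any pair of cultures enter it.

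**Figure D2:**
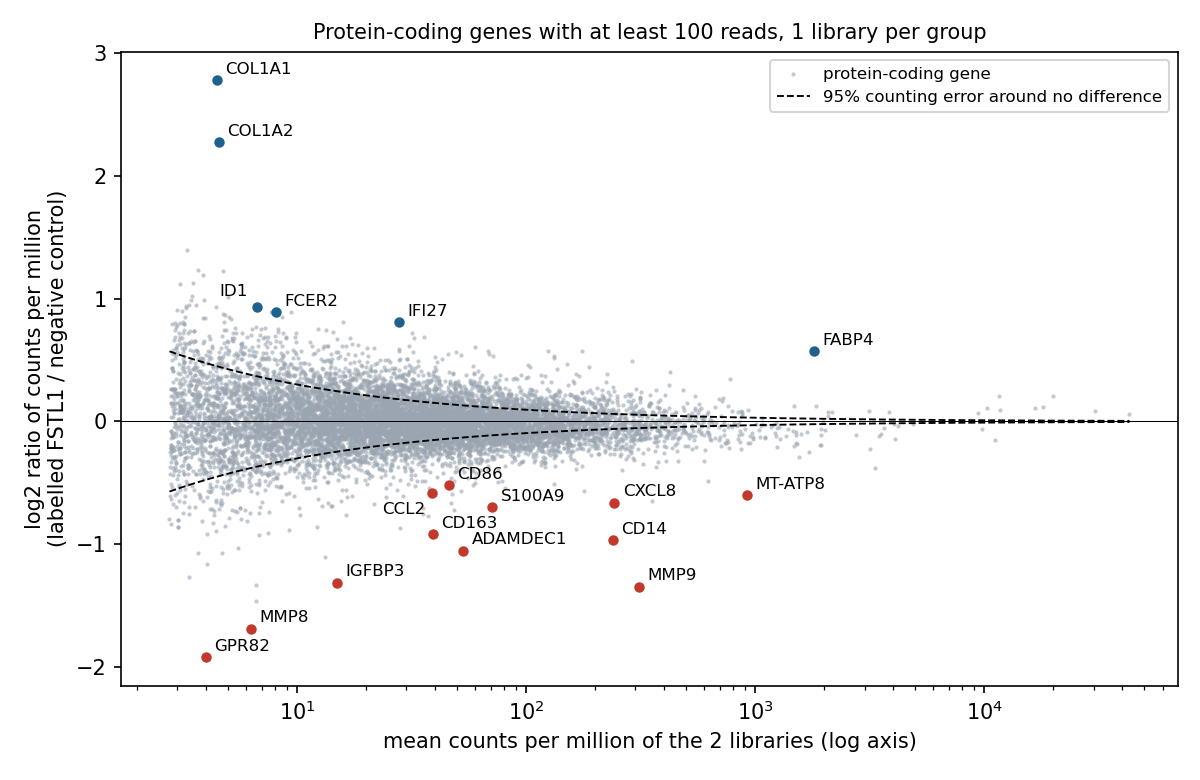
Log2 ratio of CPM, counts scaled to library totals (library labelled FSTL1 over negative control), against mean CPM (log axis) for the 10948 protein-coding genes with at least 100 reads, 1 library per group. Dashed lines mark the 95% counting error around no difference, and named genes are coloured blue where higher and red where lower in the library labelled FSTL1. COL1A1 and COL1A2 stand highest at few reads, and MMP9, CD14 and CXCL8 lie below the lines at high levels.

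Most NF-kB targets and inflammatory chemokines of the list fixed for them were lower in the library labelled FSTL1. Of 19 measured members, 17 were lower and 2 higher, and the counting interval excluded no difference for 14 of the lower and 0 of the higher. Their median log2 difference was -0.34, below all 10000 random lists matched on expression (percentile 0). The neutrophil chemoattractant CXCL8 was 1.58-fold lower (1.51 to 1.65), at 72.69 against 114.92 FPKM. CXCL3 was 2.12-fold lower (1.51 to 3.0), CCL20 was 2.70-fold lower on 16 against 48 reads (1.51 to 5.09), and the early response gene IER3 was 1.58-fold lower (1.31 to 1.91). CXCL3 belongs to a family of similar chemokines whose reads may be split in counting.

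Of the 6 measured neutrophil markers 5 were lower, with a median of -0.61 (percentile 0). The alarmin genes S100A9 and S100A8 were 1.62-fold (1.49 to 1.76) and 1.46-fold (1.27 to 1.68) lower, and S100A12 was 2.70-fold lower on 9 against 27 reads (1.23 to 6.52). The remaining member, the granulocyte colony-stimulating factor receptor gene CSF3R, named after its value was seen, was 1.23-fold higher (1.08 to 1.41). M1 markers had a median of -0.11 (percentile 1.57), with 9 of 12 measured members lower. CCL5 was 1.26-fold lower (1.19 to 1.34), GBP1 was 1.17-fold lower (1.08 to 1.28) and TNF had 145 against 200 reads, a ratio whose interval included no difference. FCGR1A, the high-affinity IgG receptor, was 1.33-fold higher (1.18 to 1.5), a value made uncertain by near-identical copies and an overlapping antisense gene. The M1 cytokine gene IL6 had 0 reads in both libraries, which allows up to 0.178 and 0.160 CPM, and IL12B had 1 and 0 reads. The M1 list lay within the random lists under 4 of the 12 alternative settings.

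M2 markers went both ways. Of 21 measured members 9 were higher and 12 lower, with a median of -0.02 (percentile 46.5). The haemoglobin scavenger receptor CD163 was 1.89-fold lower (1.69 to 2.11), next to a neighbour, CD163L1, that overlaps it on the same strand. FN1, which encodes fibronectin, was 1.56-fold lower (1.51 to 1.62), and FCER2, the low-affinity IgE receptor, was 1.86-fold higher (1.45 to 2.38). TGM2, a transglutaminase commonly used as an M2 marker, was abundant at 248.33 and 248.45 FPKM. The lipid carrier gene FABP4, also on this list, was higher, at 1577.7 against 1061.2 FPKM and 36405 against 27212 reads. Its counting intervals in the 2 libraries did not overlap. TGM2 and FABP4 were named after their values were seen.

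Genes of the extracellular matrix and its proteases had a median of -0.25 (percentile 0), with 10 of 13 measured members lower. Besides MMP9 and FN1, the protease MMP7 was 1.51-fold lower (1.37 to 1.67) and the protease inhibitor TIMP3 was 1.42-fold lower (1.30 to 1.55), while the basement membrane collagen genes COL4A1 and COL4A2, named after their values were seen, were 1.34-fold (1.21 to 1.49) and 1.17-fold (1.10 to 1.25) higher. Without the minimum of 1 FPKM the list held 23 genes and its median turned to 0.078, above its random lists (percentile 98.5), as genes of few reads entered it, collagen genes among them. The fibroblast marker list, which shares 5 genes with other lists and of which no member reached 1 FPKM, had a summed count of 485 in the library labelled FSTL1 and of 117 in the control, a ratio of 4.61 (3.76 to 5.69). COL1A1 had 132 against 21 reads, COL1A2 128 against 29 and COL3A1 83 against 9, differences of 6.99-fold (4.39 to 11.7), 4.91-fold (3.26 to 7.62) and 10.2-fold (5.15 to 23.2).

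Glycolysis and hypoxia, cholesterol synthesis, dendritic cell, allergy and histone lists also lay below their random lists. Of 16 glycolysis and hypoxia genes 15 were lower, with a median of -0.16 (percentile 0.03). The hypoxia-induced peptide gene ADM was 1.63-fold lower (1.31 to 2.03), the glucose transporter SLC2A1 was 1.29-fold lower (1.22 to 1.37), and the glycolytic enzymes PKM and TPI1 were 1.22-fold (1.20 to 1.24) and 1.16-fold (1.11 to 1.21) lower. Cholesterol synthesis genes had a median of -0.11 (percentile 0.78), with 15 of 18 lower, among them DHCR7 at 1.32-fold (1.15 to 1.52) and SQLE at 1.23-fold (1.15 to 1.31). Dendritic cell markers had a median of -0.28 (percentile 0.19), with 4 of 6 lower and 2 higher. The lipid-presenting molecules CD1C and CD1A were 1.62-fold (1.33 to 1.97) and 1.75-fold (1.14 to 2.73) lower, while the IgE receptor chain FCER1A, named after its value was seen, was 1.24-fold higher (1.05 to 1.47). Allergy mediators and receptors had a median of -0.12 (percentile 0.75), with 10 of 15 lower, and the leukotriene synthesis genes ALOX5AP and ALOX5 were 1.31-fold (1.22 to 1.42) and 1.29-fold (1.13 to 1.47) lower. Replication-dependent histones, whose transcripts mostly lack poly(A) tails and so follow the RNA selection, had a median of -0.33 over 8 near-identical and therefore uncertain genes (percentile 0.01). Higher members whose interval excluded no difference were ALDOC in the glycolysis list, STARD4 in the cholesterol list and FCER2 and FCER1A in the allergy list. The allergy list lay within the random lists under 3 alternative settings, the cholesterol list under 2 and the dendritic list under 1.

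Interferon-stimulated and mitochondrially encoded genes were higher in the library labelled FSTL1. Of 18 type I interferon response genes 15 were higher, with a median of 0.13 (percentile 99.3), and the interval excluded no difference for 10 of the higher and 0 of the lower. IFI27 was 1.76-fold higher (1.54 to 2.0), the ubiquitin-like modifier ISG15 was 1.5-fold higher (1.23 to 1.82), the antiviral GTPase MX1 was 1.75-fold higher (1.47 to 2.09) and IFI44 was 1.36-fold higher (1.20 to 1.53). With a minimum of 5 FPKM this list kept 9 genes and lay at percentile 94.7. Of the 13 mitochondrially encoded genes 12 were higher, with a median of 0.09 (percentile 99.9), led by MT-ND2 and MT-ND1 at 1.15-fold each (1.15 to 1.16), and MT-ATP8 was lower at 3523.62 against 5345.19 FPKM. MT-ATP8 is 207 bases long and overlaps MT-ATP6 on the same strand, which was 1.05-fold higher (1.04 to 1.06). The lower value of MT-ATP8 may therefore depend on how shared reads were counted, which was not tested. Against random lists without matching on expression the mitochondrial list lay at percentile 93.9. Mitochondrial genes took 20.7% of the counts in the library labelled FSTL1 (20.68% to 20.72%, exact Clopper-Pearson) and 19.2% in the control (19.23% to 19.26%). Ribosomal protein genes had a median of -0.01 and a mean of 0.0034 over 50 genes, yet lay at percentile 98.3, since random lists of equally expressed genes had lower medians still. The ribosomal list lay at percentile 42.2 without that matching and at 96.8 with no FPKM minimum.

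**Figure D3:**
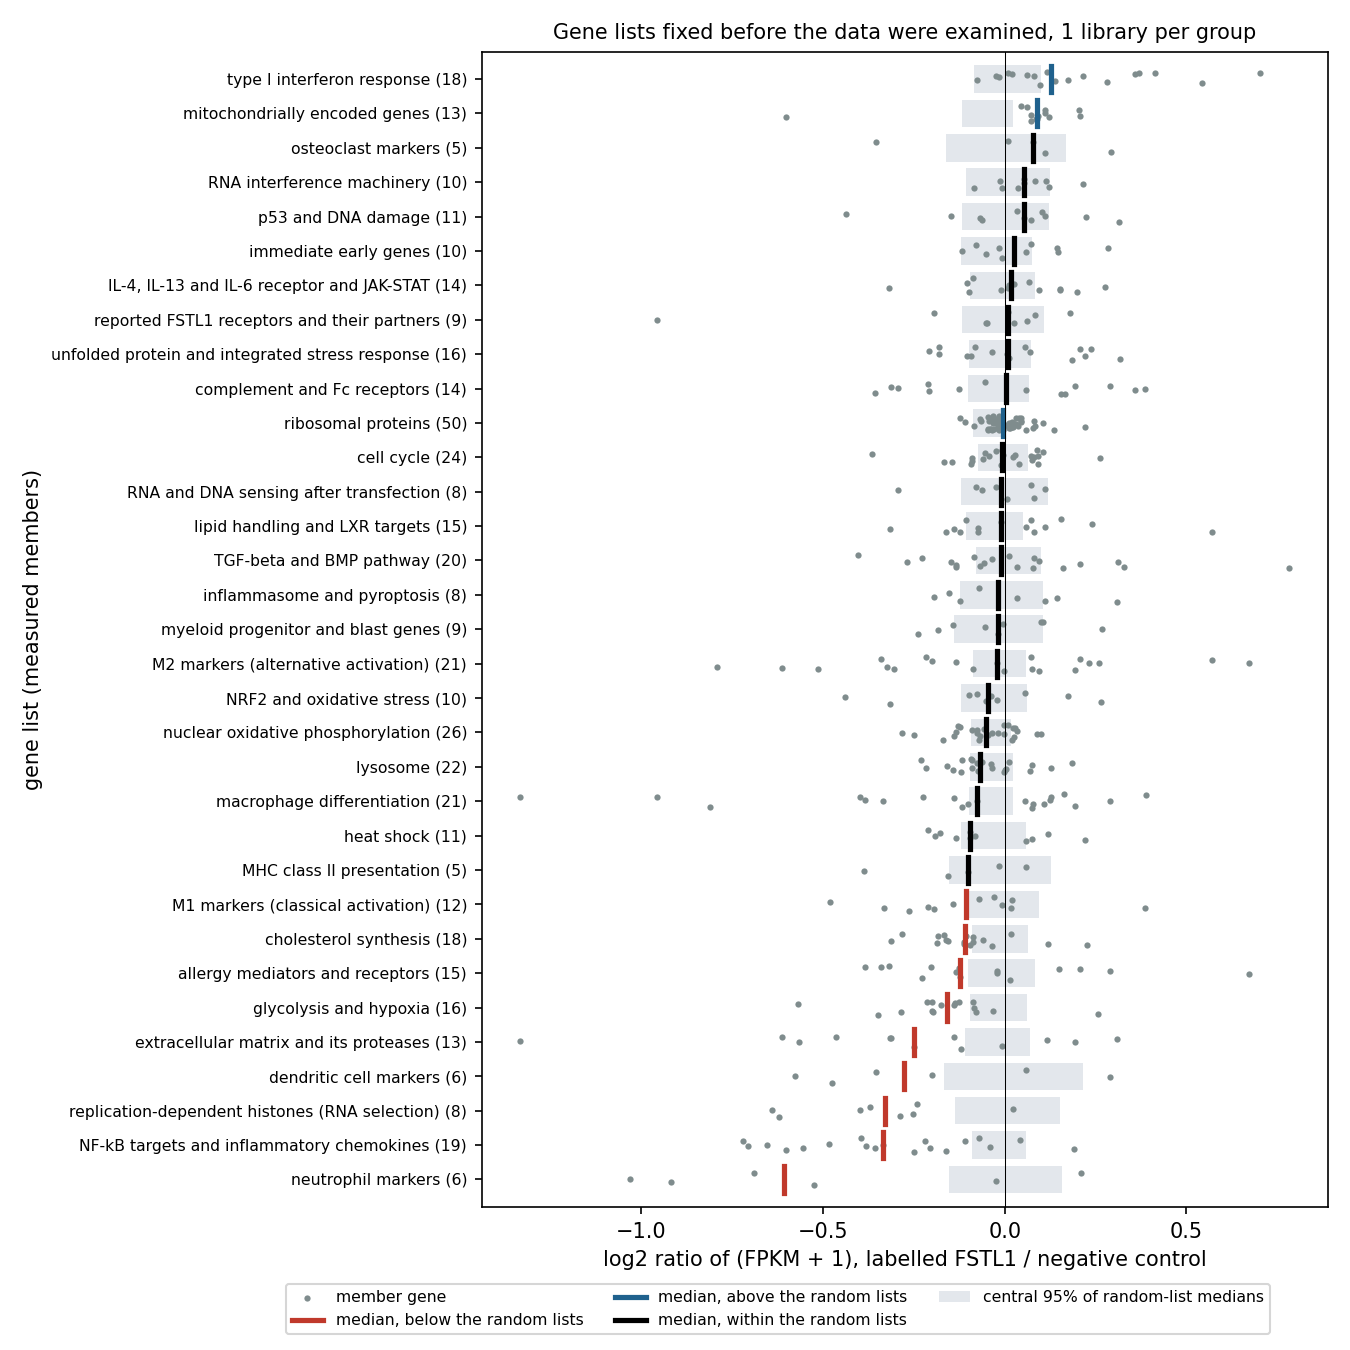
Log2 ratio of (FPKM + 1), library labelled FSTL1 over negative control, for the members (points) and medians (bars) of 33 gene lists, with the central 95% of medians of matched random lists in grey. In all, 9 medians lie below the grey range and 3 above it, with the neutrophil list lowest at -0.61 and the interferon list highest at 0.13.

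Genes of the pathways closest to FSTL1 went both ways. On the list fixed for it, TGF-beta and BMP pathway genes had a median of -0.01 (percentile 34.9) and a mean of 0.03, with 10 of 20 members higher and 10 lower. The wider TGF-beta signalling pathway of the deposited annotation had 34 of 56 genes lower and a median of -0.06, below its random lists (percentile 0.83). That annotation also assigns noncoding genes to the pathway, with LINC00674 among its lowest, so this median is not of established pathway genes alone. The BMP target ID1 was 1.91-fold higher (1.46 to 2.52), the repressor gene SKIL was 1.37-fold higher (1.18 to 1.58) and the receptor gene TGFBR2 was 1.40-fold lower (1.25 to 1.56). Reported FSTL1 receptors and their partners had a median of 0.01 (percentile 64.5) but a mean of -0.10, which CD14 lowered, and the median was below 0 on the TPM scale and with upper quartile scaling. CD14, the lipopolysaccharide co-receptor (ENSG00000170458, chromosome 5, 140631728 to 140633700, minus strand), was 1.95-fold lower (1.86 to 2.04), at 98.67 against 192.54 FPKM. IRAK1 was 1.15-fold lower (1.10 to 1.20) and IRAK4 1.15-fold higher (1.05 to 1.26).

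Of the 33 lists with at least 5 measured members, 12 lay outside the central 95% of their random lists, where 1.65 would by chance if genes varied independently, and 21 lay within it. The median was -0.08 for macrophage differentiation (percentile 11.2), whose mean of -0.16 lay below its random lists (percentile 0.02). It was -0.07 for the lysosome (percentile 14.8), -0.05 for nuclear oxidative phosphorylation (percentile 31.8), -0.09 for heat shock (percentile 8.86), -0.10 for MHC class II presentation (percentile 12.0) and -0.05 for NRF2 targets (percentile 38.7). Near 0 stood the cell cycle at -0.01 (percentile 45.9), myeloid progenitor genes at -0.02 (percentile 51.3), inflammasome genes at -0.02 (percentile 46.4; mean 0.0077), lipid handling at -0.01 (percentile 70.0; mean 0.02) and nucleic acid sensing at -0.01 (percentile 46.2). Complement and Fc receptor genes stood at 0.0035 (percentile 71.3), the IL-4, IL-13 and IL-6 receptor and JAK-STAT list at 0.02 (percentile 71.6), the unfolded protein response at 0.01 (percentile 72.2) and immediate early genes at 0.03 (percentile 85.6), and these 4 medians were below 0 on the TPM scale and with upper quartile scaling. The RNA interference machinery stood at 0.05 (percentile 80.4), p53 targets at 0.05 (percentile 82.0) and osteoclast markers at 0.08 (percentile 81.8). Of the 7 lists with too few measured members, summed counts in the library labelled FSTL1 and the control were 243 and 274 for metallothioneins, 446 and 465 for T and NK cell markers, 45 and 64 for B cell markers, 236 and 299 for epithelial markers, 2951 and 3421 for endothelial markers and 3 and 2 for erythroid markers, besides the fibroblast markers given with the matrix genes.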

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

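The settings of protein-coding genes only, at least 100 reads and removed GC and length trends were chosen after seeing the data. FSTL1, CD86 and MRC1 kept their direction under each pseudocount and scaling, with log2 differences of 0.03 to 0.49, -0.54 to -0.38 and 0.07 to 0.46, but the counting interval of MRC1 included no difference on the TPM scale (0.981 to 2.01) and with upper quartile scaling (0.983 to 2.01). The counts of genes at least 2-fold apart, 146 higher and 127 lower, depended on the setting: 323 and 238 with a pseudocount of 0.1, 3 and 4 with a pseudocount of 5, 15 and 17 with at least 5 FPKM, 348 and 268 at 1.5-fold, 7 and 9 at 4-fold, and 208 and 196 on the TPM scale. By counting intervals 1893 genes were higher and 1994 lower. Among protein-coding genes 0 were higher and 5 lower, and with at least 100 reads 0 and 4. The fold thresholds, the interval criterion and the filters, which leave fewer genes, move these counts by construction, and for the pseudocounts and the TPM scale the cause was not tested. Lists above their random lists numbered 3, 1 without matching on expression, 2 with at least 5 FPKM and 4 with no FPKM minimum. Lists below numbered 9, but 8 without matching, with at least 100 reads or with GC and length trends removed, and 7 with a pseudocount of 5. They numbered 6 with means over members, 6 with no FPKM minimum and 5 with at least 5 FPKM, where fewer genes were tested. The NF-kB and glycolysis lists lay below their random lists under each of the 12 alternatives. The matrix list was reversed to 0.078 with no FPKM minimum (percentile 98.5), where it held 23 genes in place of 13, and the ribosomal median to 0.0034 as a mean and 0.0239 with GC and length trends removed; the cause of the latter pair was not tested. Scaling moved the median gene by -0.04 (TPM), 0.0025 (median ratio) or -0.03 (upper quartile). No replicate could be left out, since the table has 1 column per sample. No paired analysis was possible because each group has 1 library.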

Other observations

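The tests of whole tissue, of GC content and length, of counting noise, of the share of macrophages and of genes neighbouring CAP1 were chosen after the result was seen, and the test of fibroblast markers before. The pathway annotation in the deposited table, which places pseudogenes and noncoding genes in some pathways, gave a mixed picture of inflammation. Of 283 pathways with 10 to 150 measured genes, 29 had a median below the central 95% of matched random lists and 1 above it, where 7.08 would lie on each side by chance if genes varied independently. IL-17 signalling, a pathway of chemokine and protease induction, had 52 of 71 genes lower in the library labelled FSTL1 (median -0.08, percentile 0.01), and cytokine-receptor interaction 77 of 113 (median -0.07, percentile 0.03). Among others, rheumatoid arthritis (percentile 0.24), viral protein interaction with cytokines (0.64) and cytosolic DNA sensing (1.17) also lay below. These pathways share genes and are not separate findings. CXCL3, CCL20, CXCL8 and CCL2, all on the NF-kB list, were among the lowest genes of each one named so far except cytosolic DNA sensing. TNF signalling (percentile 2.52), NF-kappa B signalling (5.55), Toll-like receptor signalling (9.15) and chemokine signalling (percentile 9.46) lay within their random lists. The 29 also held pathways outside inflammation, such as the one annotated "Autophagy - other" (0.66), Hedgehog signalling (1.37), RNA polymerase (1.41) and fatty acid elongation (2.13). The pathway above was ether lipid metabolism, with 13 of 20 genes higher (median 0.13, percentile 99.6). The lipid carrier FABP4, a member of the M2 list, was among the most abundant transcripts, at 1577.7 FPKM in the library labelled FSTL1 and 1061.2 in the control.

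COL1A1 and COL1A2, collagen genes that macrophages hardly express, were higher in the library labelled FSTL1, at 0.87 and 0.70 FPKM. A candidate explanation is a trace of fibroblast RNA or reads in that library, since the other 8 fibroblast markers, fixed before the data were examined, summed to 225 against 67 reads, a ratio of 3.73 (2.83 to 4.98), with no gene at 1 FPKM, 5 of the 10 list genes also in the matrix list and no sort or gate named. COL3A1 (0.73 FPKM), DCN and LUM carried most of it, with 138 against 15 reads, while the other 5 markers had 87 against 52, a ratio of 1.86 (1.30 to 2.67), and the intervals of PDGFRA, PDGFRB, THY1 and ACTA2 each included no difference. Whole tissue cannot be told apart from this: in 0 of 5 lists of other cell types did the counting interval of the summed ratio lie above no difference, but 3 of them have a baseline in both libraries that would hide a small share, leaving B cell markers (45 against 64 reads) and erythroid markers (3 against 2). FSTL1 is itself abundant in fibroblasts, and its excess of 15.7 reads over the control stands beside 113 for COL1A1, so its count may carry the same trace, while collagen expression by the THP-1 cells stays open.

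The lower NF-kB targets and chemokines in the library labelled FSTL1 were set against 3 technical explanations. Removing trends with GC content and gene length left the list at percentile 0 (median -0.28, 18 genes), and so did keeping only its 12 members with at least 500 reads (percentile 0, median -0.21), which argues against both as the whole cause. A smaller share of differentiated macrophages cannot be told apart from the pattern. The macrophage list had a median of -0.0755, with a bootstrap interval of -0.23 to 0.11 that lay above the NF-kB median of -0.34. The myeloid progenitor median of -0.02 was not above 0, where a smaller share would put it. That median covered 9 of 14 listed genes and left out KIT, which had 15 against 0 reads but was below 1 FPKM. The summed counts of the progenitor list had a ratio of 0.975 (0.948 to 1.003). But macrophage list members went both ways, 10 higher and 11 lower, and their mean of -0.16 lay at percentile 0.02. Their SD of 0.43 was wider than the gap of 0.26 to the NF-kB median, but it is the spread of single genes and not the error of the median. This test was first run without MMP9, MMP12 and CD14, which gave a median of 0.07. An effect of the transfected construct and a difference between the cultures or their preparation also stay open with 1 library per group, and neither was tested.

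CAP1, an actin-binding protein gene on chromosome 1, had the most reads of any nuclear gene in both libraries, at 2771.49 and 3082.72 FPKM, and its neighbour PPT1 stood at 1154.17 and 1272.99 FPKM. A gain of copies of the region in THP-1 is a candidate explanation, and would raise the other genes nearby. Their median FPKM lay at percentile 94.0 of equally sized gene windows within 100 kb and 91.9 within 200 kb. It lay at 96.8 within 300 kb and 99.9 within 500 kb, so the answer turned on the window. These medians rested on 2, 6, 11 and 16 other genes. The windows took both sides of CAP1 together, and levels around it were uneven. On the PPT1 side, the mean FPKM of the 2 libraries was 478.4 for SMAP2 and 211.1 for ZMPSTE24. It was 139.9 for COL9A2 and 80.0 for RLF, but 1.3 for TMCO2 and 7.79 for ZFP69B. On the other side it was 23.0 for TRIT1 and 2.02 for MYCL but 83.4 for PABPC4. A gain reaching only the PPT1 side was therefore not tested. The high levels of CAP1 and PPT1 are common to both libraries, and no biological explanation was tested.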
